A study of Mus musculus with 2 samples.

How the data were processed

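H3K27me3 was measured by ChIP-seq in mouse hindbrain at embryonic day 15.5, in 1 group of 2 biological replicates pooled from 78 and 62 embryos of both sexes, each with 2 technical replicates, per the labels. The deposited data were 4 narrowPeak lists on mm10: 1 per replicate, 1 called on the pooled replicates, and 1 of replicated peaks. Per the deposited descriptions, the lists of replicate 1 and of the pooled replicates were made with 2 control files and that of replicate 2 with 1, and the replicated list was derived from the pooled list and both replicates' own lists. The aligner, the peak caller, its threshold and the rule for a replicated peak are not given in the sources used here. The signal value of each peak was deposited as the peak caller's own enrichment measure, and whether it is a fold over the control is not given in the sources used here. The −log10 p and −log10 q values of each peak were likewise deposited as the caller gave them. Signal and −log10 p ranked or described peaks within a list and were not compared between lists. Read counts were not analysed here, so the depth of each library is unknown. A difference in the number of peaks between replicates can therefore come from depth, from the controls or from the tissue.

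The reference was GRCm38, the assembly that mm10 names, with the GENCODE M21 annotation, and each peak ended within the length of its chromosome. Peaks on autosomes and X were used, with 1 peak on an unplaced contig left out of the replicate 1 list and 1 out of the pooled list. No list had a peak on Y, and 183 genes on Y were left out. Coordinates are 1-based. A gene was counted as marked when at least 1 bp of a peak lay within 1000 bp of the TSS of any of its protein-coding transcripts, for 21670 protein-coding genes. The covered share was the percent of bases under peaks in a window of 5 kb on each side of the gene's most covered TSS, or for Hox genes over the gene body with 1 kb on each side. Because the best TSS was taken, genes with many TSSs had more chances of a high value. A high-CpG promoter had a CpG observed/expected ratio of at least 0.6 and a GC share of at least 0.5 within 500 bp of the TSS. Peaks were placed by midpoint in promoters, exons, introns or intergenic sequence, in that order. Shuffled peaks kept their chromosome and width and avoided runs of at least 1000 unknown bases, in 100 seeded shuffles. Domains joined peaks with gaps of up to 3 kb.

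The share of marked genes in each of 32 gene lists was compared with all other genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the lists, at a threshold of 0.05. The lists comprised 3 groups of Hox paralogs, regulators of hindbrain, forebrain, mesoderm, endoderm and epidermis, markers of blood, vessels, neurons, progenitors, oligodendrocytes and neurotransmitter identity, housekeeping, cell cycle inhibitor, Polycomb, ligand, germline and imprinted genes, and 10 gene families. Covered shares were compared by two-sided permutation tests of the difference of means, exact for Hox genes and with 100000 resamples for the regional regulators. The 5 comparisons between lists were adjusted together. Genes were the units of these tests, so their p-values describe lists of genes in this tissue and not a difference between conditions. The list test was tested on simulated data with the 21670 genes and lists of 20: planted shares of 30%, 50% and 80% marked were called in 40.2%, 94.6% and 100% of 500 lists each, and unchanged lists in 0.733% of 1500. The simulated lists were random genes marked independently of each other. The real lists held from 7 to 1091 genes, and some are of neighbouring genes under shared domains, so these rates need not hold for them.

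Named genes followed a rule: the 20 most covered genes marked in both replicates, the 10 of the highest promoter signal, the genes in the 5 widest domains, up to 4 marked members of the highest signal and up to 3 unmarked members of each list, any Hox gene, and the 5 of the highest signal among genes marked by each replicate alone. Genes named outside it are Meis1, Meis2, Pbx1, Pbx3, those in the domains beyond the fifth, and the gene families and noncoding genes of the closing section, all chosen after their values were seen, and Pbdc1, Car5b, Mid1 and Bgn, the members with a peak of a list of escape genes set before its test. The groups, the gene lists, the tests, the rule and most alternatives were set before the data were examined. Alternatives changed the promoter window (500 or 2500 bp on each side), the overlap (50% of the window or peak), the TSS definition, the peak list, the threshold (the 50% of peaks with the best p), the joining gap (1 or 10 kb), the covered window (2 kb on each side) and the background (high-CpG promoters), and left out each replicate in turn by using the other's own list. The mean ± SD over replicates came from their own lists. Computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.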

Results

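Trimethylation of lysine 27 of histone H3 (H3K27me3), the mark placed by Polycomb repressive complex 2 on silent developmental genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hindbrain of B6NCrl mouse embryos at embryonic day 15.5. The samples form 1 group with 2 biological replicates, pools of both sexes from 78 embryos (replicate 1) and 62 embryos (replicate 2), so no second condition was compared. The data were 4 peak lists on the mm10 build: 1 for each replicate, 1 from the pooled replicates and 1 of replicated peaks. Read counts per library were not analysed here, so the depth behind each list is unknown and no counting interval is given for a peak. Replicate 1 had 63373 peaks on the assembled chromosomes, covering 27.6 Mb or 1.01% of their length, and replicate 2 had 28948 peaks covering 13.1 Mb or 0.482%. The mean was 46160.5 ± 24342 peaks (SD, n = 2), and replicate 1 had 2.19 times as many as replicate 2. The replicated list held 26040 peaks of median width 472 bp, covering 19.4 Mb, and it is the list used below unless another is named. Values called signal below are the peak caller's own, as deposited, and rank peaks within 1 list only.

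The replicates were compared to ask how far they mark the same places. Of the replicate 2 peaks, 21365 (73.8%) overlapped a replicate 1 peak by at least 1 bp, against a mean of 2.11% in 100 within-chromosome shuffles. Of the longer replicate 1 list, 18060 (28.5%) overlapped a replicate 2 peak, against 1.07% in the shuffles. With equal numbers of top-ranked peaks from each replicate the shares were 47.0% for replicate 1 and 60.4% for replicate 2. Over the full lists the Jaccard index of covered bases was 0.318, against a shuffled mean of 0.0038. The strongest peaks were shared in nearly every case: of the top 1000 by p-value, 100% of replicate 1 and 99.7% of replicate 2 peaks met the other list, and of the top 5000 the shares were 94.0% and 97.9%. Unshared peaks had lower median −log10 p and width than shared peaks within each list. In replicate 1 the medians were 4.33 and 250 bp, against 6.89 and 511 bp for shared peaks. In replicate 2 they were 3.94 and 229 bp, against 5.23 and 352 bp. Every replicated peak was found unchanged in the pooled list, 16035 (61.6%) met both replicates' own lists, and 884 (3.39%) met neither.

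H3K27me3 stood at the promoters of 2749 of 21670 protein-coding genes (12.7%), counting a gene as marked when a peak lay within 1 kb of any of its transcription start sites (TSSs). Below, an unmarked gene is one with no such peak in the replicated list. Replicate 1 marked 3646 genes and replicate 2 marked 2550, a mean of 3098 ± 775 (SD, n = 2). The replicates had 2389 marked genes in common, where independent lists would share 429. Requiring 50% of the window to be covered left 1353 genes. By midpoint, 13.7% of replicated peaks lay in a promoter window, 5.29 times the shuffled mean of 2.59 ± 0.0981% (SD, 100 shuffles). Exons outside promoters held 8.02% (1.88 times the shuffled mean), introns 37.3% (0.906 times) and intergenic sequence 41.0% (0.789 times). The promoter share was 9.47% in replicate 1 and 14.7% in replicate 2.

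Among genes marked in both replicates, the 20 with the most completely covered TSS surroundings included Six3, Cdx2 and Neurog3. The covered share of the 10 kb around the best TSS was 100% at Six3, a homeobox gene of the anterior forebrain and eye (chromosome 17, 85613608 to 85629302), and 94.3% ± 4.86 over the replicates' own lists (SD, n = 2). It was 99.5% at Cdx2, a caudal and intestinal regulator (chromosome 5, 147300805 to 147307270; replicates 92.2% ± 9.19), and 99.4% at Neurog3, required for pancreatic endocrine cells (chromosome 10, 62133090 to 62134763; replicates 94.3% ± 4.35). Hmx1 (99.0%), Lhx6 (98.7%), the mesodermal gene T (98.6%), Pax9 (97.5%), Hoxd12 (97.2%), Foxl1 (97.0%), Hoxd11 (97.0%), Tfap2d (96.9%), Foxa1 (96.8%), Neurog1 (96.8%), Foxf2 (96.7%) and Hoxb13 (96.6%) followed. The others were Gfy (99.1%), Matn4 (98.5%), Crlf1 (97.1%), the imprinted thyroid hormone deiodinase Dio3 (96.7%) and Ltbp4 (96.5%). Ranked by signal at the promoter instead, Cyp26c1, an enzyme that degrades retinoic acid, came first at 8.51 (chromosome 19, 37685581 to 37693398). Klf14 (8.46), Six3 (7.58), Ccno (7.42), Osr1 (7.34), 2210011C24Rik (7.31), Otx2 (7.24) and Dio3 (7.03) followed. Then came Fam241b and Neurog3 (both 6.96), whose promoter windows overlap and hold the same highest signal. This ranking is of the replicated list and need not hold in the replicates' own lists. The signal of Ccno was 3.23 in replicate 1 and 3.01 in replicate 2, near the medians of shared peaks there (3.20 and 2.98). Klf14 had 7.37 and 4.73 and Dio3 had 6.10 and 3.77, whereas Osr1 had 6.84 and 7.38.

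Hox genes pattern the body axis from hindbrain to tail. Their paralog groups were compared because paralogs 1-5 include Hox genes used in hindbrain, which lies anterior to the domains of paralogs 10-13. Expression in this tissue was not measured here. All 12 genes of paralogs 6-9 and all 12 of paralogs 10-13 were marked, and 14 of 15 of paralogs 1-5. Peaks covered 58.5% ± 26.1 of gene bodies with 1 kb on each side in paralogs 1-5 (SD, n = 15 genes), 82.4% ± 12.04 in paralogs 6-9 (n = 12) and 91.0% ± 10.7 in paralogs 10-13 (n = 12). The difference of paralogs 1-5 from paralogs 10-13 was −32.5 percentage points (two-sided exact permutation p = 0.000215, Benjamini-Hochberg adjusted p = 0.00108 over 5 comparisons between gene lists) and that from paralogs 6-9 was −23.9 points (exact permutation p = 0.00524, adjusted p = 0.0131). The difference from paralogs 10-13 was −28.9 points in replicate 1 (exact permutation p = 0.000532) and −40.1 points in replicate 2 (exact permutation p = 3.62e-05). The difference in marked genes between paralogs 1-5 and 10-13 was not past the threshold (Fisher's exact p = 1). Genes of a cluster are neighbours and some of their records overlap, so they are not independent replicates. The record of Hoxc5 spans Hoxc9, Hoxc8, Hoxc6 and part of Hoxc10, and that of Hoxa3 spans Hoxa6. The mean of paralogs 1-5 therefore includes sequence of the groups it is compared with.

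Hoxa2 and Hoxb2, which act in the anterior hindbrain segments, were the least covered Hox genes. Hoxa2 (chromosome 6, 52162417 to 52164831) was covered over 5.19% of its body and had no promoter peak in the replicated list, though replicate 2 alone marked it, with replicate values of 7.43% ± 3.56 (SD, n = 2). Hoxb2 (chromosome 11, 96350525 to 96354012) was covered over 6.01%, with 7.27% in replicate 1 and 0% in replicate 2. The neighbouring paralogs were more covered, Hoxa1 over 71.4% and Hoxb1 over 87.7%. Without Hoxa2 and Hoxb2, a comparison added after these values were seen, the other 13 genes of paralogs 1-5 averaged 66.6% ± 16.1 and the difference from paralogs 10-13 was −24.4 points (exact permutation p = 0.000328). Among posterior genes, Hoxb13 and Hoxd12 were covered over 100%, Hoxd10 over 98.9%, Hoxc10 over 97.0% and Hoxa13 over 65.5%. Over whole clusters, from the first to the last Hox gene, the covered share was 89.4% for Hoxc (chromosome 15, replicates 82.8% ± 7.15), 73.0% for Hoxd (chromosome 2, 63.3% ± 15.1), 67.5% for Hoxa (chromosome 6, 59.5% ± 12.4) and 62.8% for Hoxb (chromosome 11, 54.1% ± 13.4; SD, n = 2 throughout).

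**Figure D1:**
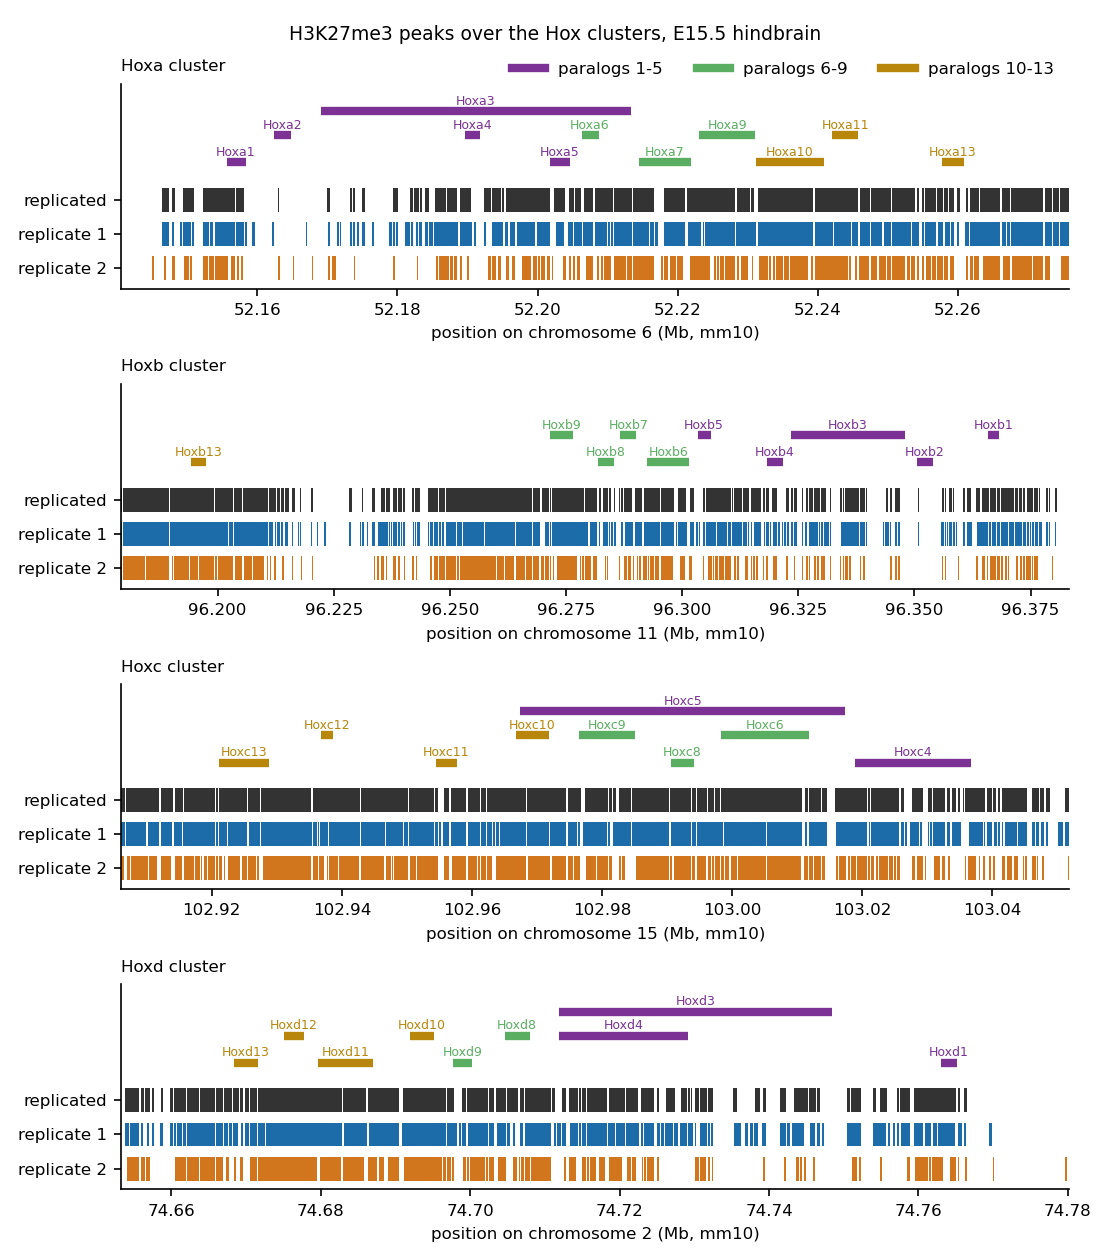
Map of H3K27me3 peaks over the Hoxa, Hoxb, Hoxc and Hoxd clusters and their flanks (x axis, position in Mb on mm10); rows show the peaks of the replicated list, replicate 1 and replicate 2, and coloured bars show the Hox genes by paralog group. Peaks are sparse over Hoxa2 and Hoxb2 and cover 91.0% of the bodies of paralogs 10-13 on average, with whole-cluster coverage between 62.8% and 89.4% in the replicated list.

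Transcription factors of the hindbrain were compared with those of the forebrain, the same class of gene from this region and from another. Forebrain factors were marked in 29 of 30 cases (96.7%) and hindbrain factors in 27 of 35 (77.1%), both above the 12.7% of all genes (adjusted exact p = 2.45e-24 and 2.95e-17, Fisher's exact test). Peaks covered 73.9% ± 19.7 of the 10 kb around the TSS of forebrain genes (SD, n = 30) and 57.8% ± 27.9 of hindbrain genes (n = 35), a difference of −16.1 percentage points (two-sided permutation p = 0.00934, adjusted p = 0.0156). The difference was −16.6 points in replicate 1 and −16.7 points in replicate 2 (permutation p = 0.0047 and 0.00216). Six3, Otx2 (86.6%), Emx2 (79.9%) and Dlx5 (63.5%) led the forebrain list by signal, and Hesx1 (4.19%) was its single unmarked member, marked by replicate 1 alone. In the hindbrain list the strongest promoters were those of the cerebellar gene Ptf1a (90.3%), Gata3 (84.1%), Zic4 (65.3%) and Egr2 (91.3%), the last a gene of hindbrain segments in younger embryos. Unmarked hindbrain genes included Mafb, where peaks covered 52.5% of the window but not the promoter itself, Zic1 (26.2%) and Zic2 (33.7%), both marked by replicate 1 alone.

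Among the hindbrain genes were 4 at 0%, Meis1, Meis2, Pbx1 and Pbx3, Hox cofactors that are also used outside the hindbrain. They were singled out after their values were seen: each was at 0% in the replicated list and marked in neither replicate. Leaving them out of the hindbrain list alone was therefore bound to shrink the difference. Without them the hindbrain mean was 65.3% ± 19.5 (n = 31) and the difference of −8.68 percentage points did not pass the threshold (permutation p = 0.0872). The difference in marked genes (Fisher's exact p = 0.0312, adjusted p = 0.0389) ended without these genes (27 of 31, Fisher's exact p = 0.354), and it did not pass in replicate 1 alone (Fisher's exact p = 0.0566) or in replicate 2 alone (Fisher's exact p = 0.0925).

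**Figure D2:**
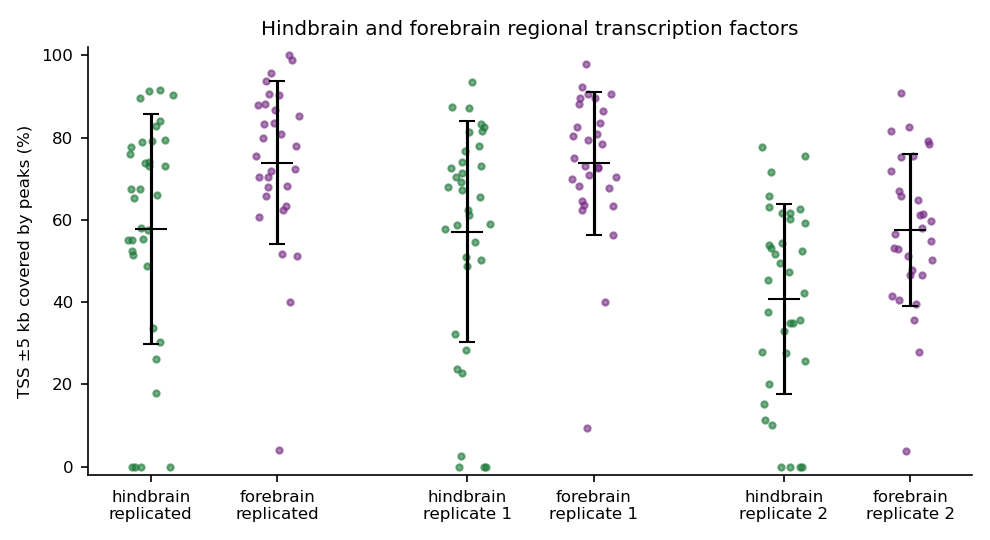
Share of the 10 kb around the TSS covered by peaks (y axis, percent) for 35 hindbrain and 30 forebrain transcription factors in the replicated list and in each replicate; points are genes, horizontal bars the means and error bars the SD over genes. For each replicate, points use the best TSS of the replicated list, and bars use the best TSS of the replicate's own list. Hindbrain means are 57.8%, 57.2% and 40.8% and forebrain means 73.9%, 73.8% and 57.5%, and 4 hindbrain genes lie at 0% in the replicated list.

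Of 32 gene lists fixed before the data were examined, 23 were marked more often than other protein-coding genes, 4 less often, and 5 did not pass the threshold (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the 32 lists; genes of a list are not independent replicates). Some genes are in more than 1 list, among them Six3, T and Sox10, so the calls are not independent of each other. Mesoderm and muscle factors were marked at 24 of 29 genes (adjusted exact p = 9.19e-17), led by Osr1, Tbx1 and Mesp1, while Tbx6, Msgn1 and Myf5 were unmarked with 0% of their windows covered. Endoderm factors were marked at 16 of 18 genes (adjusted exact p = 1.83e-12), led by Foxe1 (93.5% covered) and the pancreatic gene Pdx1 (88.2%), with Hnf1a and Hnf4a unmarked. Epidermis and epithelium genes were marked at 14 of 18 (adjusted exact p = 1.15e-09), among them Dlx3, Tfap2c, Ovol1 and Tfap2a, but the basal keratin genes Krt5 and Krt14 and the basal cell regulator Trp63 were unmarked. Of the unmarked genes named here, replicate 1 alone marked Hnf4a and Krt5. None of these unmarked genes had a high-CpG promoter. Osr1, Mesp1 and Pdx1 were marked without a high-CpG promoter, whereas Tbx1, Foxe1, Dlx3, Tfap2c, Ovol1 and Tfap2a had high-CpG promoters.

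**Figure D3:**
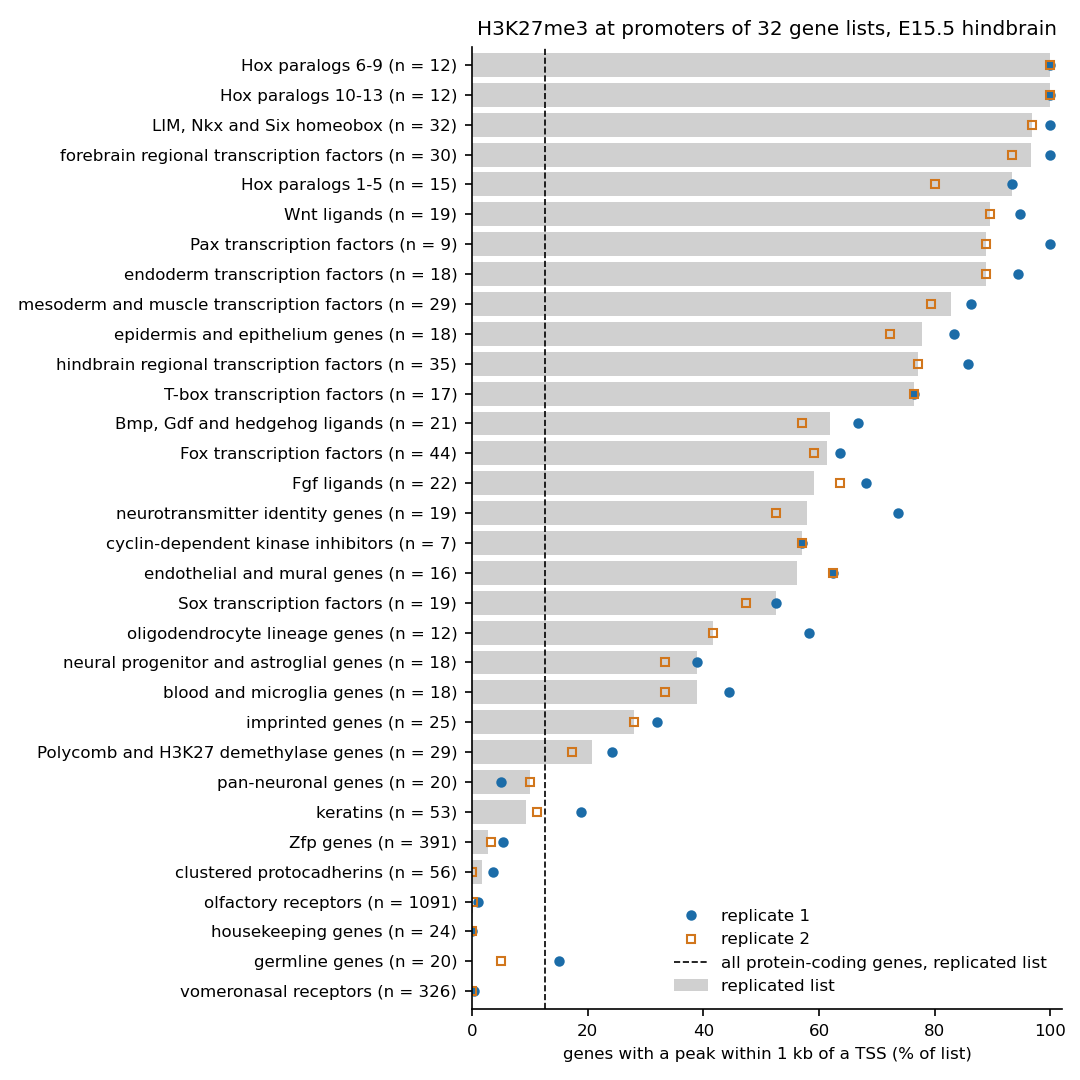
Percent of genes with a peak within 1 kb of a TSS (x axis) for the 32 gene lists (y axis, with the number of genes); bars show the replicated list, filled circles replicate 1, open squares replicate 2, and the dashed line the 12.7% of all protein-coding genes. Developmental transcription factors lie at the top, up to 100%, and receptor families and housekeeping genes at the bottom, near 0%.

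Blood and microglia genes were marked at 7 of 18 (adjusted exact p = 0.00648), with Tal1 (72.8% covered), Runx1 (85.8%), Ikzf1 (57.6%) and Gfi1 (79.0%) in front, whereas Gata1, Spi1 and Lmo2 were unmarked, the last marked by replicate 1 alone. Endothelial and mural genes were marked at 9 of 16 (adjusted exact p = 6.31e-05), including Esam, Cspg4, Fli1 (74.0%) and the VEGF receptor gene Kdr (33.8%), but not Pecam1, Cdh5 or Tek. Of the unmarked genes named from these lists, only Lmo2 had a high-CpG promoter, while Esam and Cspg4 were marked without a high-CpG promoter. The tissue holds several cell types, and a peak does not say which of them carry the mark.

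Pan-neuronal genes were marked at 2 of 20 (1 in replicate 1), Rbfox3 (55.6% covered) and Nefl (27.1%), with no difference from other genes past the threshold (Fisher's exact test, adjusted p = 1), and Tubb3, Map2 and Snap25 were at 0%. The share of Rbfox3 was 56.1% in replicate 1 and 24.4% in replicate 2, and that of Nefl was 22.5% and 12.1%. Neurotransmitter identity genes were marked at 11 of 19 (adjusted exact p = 6.42e-06). They included the dopamine transporter gene Slc6a3 (48.4%), the vesicular glutamate transporter gene Slc17a7 (63.2%), and the cholinergic pair Chat (87.7%) and Slc18a3 (82.5%), whose records overlap, whereas Slc17a8, Th and Dbh were unmarked. Of these unmarked genes, replicate 1 alone marked Slc17a8 and Th. Oligodendrocyte lineage genes were marked at 5 of 12 (adjusted exact p = 0.0147): the regulators Olig1 (94.1%), Olig2 (86.3%) and Sox10 (43.3%) and the receptor gene Pdgfra (56.4%) were covered, and the myelin genes Plp1, Mbp and Mog were at 0%. Replicate 1 alone marked Plp1 and covered 6.52% of its window. The share of Pdgfra was 67.5% in replicate 1 and 25.9% in replicate 2. Neural progenitor and astroglial genes were marked at 7 of 18 (adjusted exact p = 0.00648), with Pax6 (75.2%), Notch1 (21.4%), Slc1a3 (7.47%) and Hes1 (38.3%) in front by signal and Sox3, Sox9 (marked by replicate 2 alone) and Nes unmarked. This last call was lost in 5 settings, with adjusted exact p between 0.0529 (gene 5′ ends in place of all TSSs) and 0.462 (replicated peaks met by both replicates' own lists, an added comparison).

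Wnt ligands were marked at 17 of 19 genes (adjusted exact p = 2.9e-13), with Wnt10b covered over 95.2% of its window, Wnt1 over 78.5%, Wnt3a over 77.5% and Wnt11 over 79.7%, and with Wnt5a (marked by replicate 1 alone) and Wnt8a unmarked. Fgf ligands were marked at 13 of 22 (adjusted exact p = 6.57e-07; Fgf8 covered over 88.2%), and Bmp, Gdf and hedgehog ligands at 13 of 21 (adjusted exact p = 3.23e-07; Ihh 90.1%, Shh 69.7%). LIM, Nkx and sine oculis homeobox genes were marked at 31 of 32 (adjusted exact p = 6.18e-26), the exception being Nkx6-3, which each replicate's own list marked, and Pax genes at 8 of 9 (Fisher's exact test, adjusted p = 9.44e-07), the exception being Pax4, marked by replicate 1 alone. T-box genes were marked at 13 of 17 (adjusted exact p = 6.63e-09), Fox genes at 27 of 44 (adjusted exact p = 1.92e-13) and Sox genes at 10 of 19 (adjusted exact p = 5.27e-05). Foxn4, Foxd3, Foxd2 and Foxe3 had the strongest Fox promoters, and Sox11, Sox12 and Sox13 were at 0%.

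Cyclin-dependent kinase inhibitors were marked at 4 of 7 genes (Fisher's exact test, adjusted p = 0.00877): the senescence locus genes Cdkn2a (86.1%) and Cdkn2b (84.7%) were widely covered, Cdkn2c (32.9%) and Cdkn1a (8.6%) less so, and Cdkn1b, Cdkn1c and Cdkn2d were unmarked. The call was lost when 50% of the promoter window had to be covered (2 of 7 genes, adjusted exact p = 0.0816). Imprinted genes were marked at 7 of 25 (adjusted exact p = 0.0377), among them Igf2 (87.4%), Grb10 (89.3%), Ascl2 (72.6%) and Phlda2 (53.6%), a call lost in replicate 1 alone (8 of 25, adjusted p = 0.065), with the pooled list (adjusted exact p = 0.0707) and with TSS windows of 2500 bp on each side (adjusted exact p = 0.192). Genes for Polycomb proteins and H3K27 demethylases were marked at 6 of 29 (adjusted exact p = 0.272), including Bmi1, Phf19, Pcgf1 and Pcgf5, while the methyltransferase genes Ezh1 and Ezh2 and their partner Eed were at 0%. None of 24 housekeeping genes was marked in the replicated list (adjusted exact p = 0.0733, Fisher's exact test; unadjusted p = 0.0641), nor in either replicate. The share was below that of other genes past the threshold in replicate 1 alone (adjusted exact p = 0.029), with the pooled list (0.031) and with the windows of 2500 bp (0.0301). Germline genes were marked at 0 of 20 in the replicated list (adjusted exact p = 0.11, unadjusted p = 0.0994), 3 in replicate 1 and 1 in replicate 2. Keratins were marked at 5 of 53 (adjusted exact p = 0.7; 10 in replicate 1 and 6 in replicate 2), including the simple epithelial pair Krt8 (47.6%) and Krt18 (40.1%).

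Olfactory receptor genes were marked at 3 of 1091 (0.275%, adjusted exact p = 3.13e-59; 12 in replicate 1 and 3 in replicate 2), vomeronasal receptor genes at 0 of 326 (adjusted exact p = 8.37e-19; 1 in replicate 1 and 0 in replicate 2), Zfp genes at 11 of 391 (2.81%, adjusted exact p = 1.78e-11; 21 and 13) and clustered protocadherins at 1 of 56, Pcdhgb6 (adjusted exact p = 0.0102; 2 and 0). The 3 olfactory receptor genes marked in the replicated list were Olfr94, Olfr95 and Olfr63. The protocadherin call was lost with the pooled list (4 of 56, adjusted p = 0.0588), with 50% of the window covered (adjusted exact p = 0.0629) and among high-CpG promoters (0 of 3). These families differ in CpG content, since no olfactory receptor gene and 209 Zfp genes had a high-CpG promoter. Over all genes, 1687 of 10939 high-CpG promoters were marked (15.4%) against 1062 of 10731 others (9.9%), an odds ratio of 1.66 with a 95% interval of 1.53 to 1.8 (two-sided Fisher's exact p = 1.7e-34). The odds ratio was 1.27 in replicate 1 and 1.67 in replicate 2. Both the CpG class and the mark were taken over all TSSs of a gene, so genes with many TSSs had more chances of each. The promoters without high CpG include those of all olfactory receptor genes and all but 1 of the vomeronasal receptor genes, which were almost never marked. An odds ratio without these 2 families was not computed. Among high-CpG promoters alone, Zfp genes were still marked less often than others, and the other 3 families had 3 or fewer members to test.

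Chromosomes differed in how much of their length was covered, and the X chromosome differed between the replicates. In the replicated list, coverage ran from 3.86 kb per Mb on chromosome 3 to 15.2 kb per Mb on chromosome 19, with an autosomal median of 7.28 and 7.23 on X, a ratio of X to that median of 0.993. The ratio was 1.28 in replicate 1, 0.637 in replicate 2 and 1.57 in the pooled list. X held 10.8% of replicate 1 peaks and 6.76% of replicate 2 peaks, and it makes up 6.49% of the chromosome length. Peaks on X lay less often at promoters: 4.11% of replicated X peaks had their midpoint in a promoter window, against 14.8% on autosomes. Of the 1000 replicated peaks with the best p-values, 2 were on X. X lay above the autosomal median in 1 replicate and below it in the other, so no direction is given for X.

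**Figure D4:**
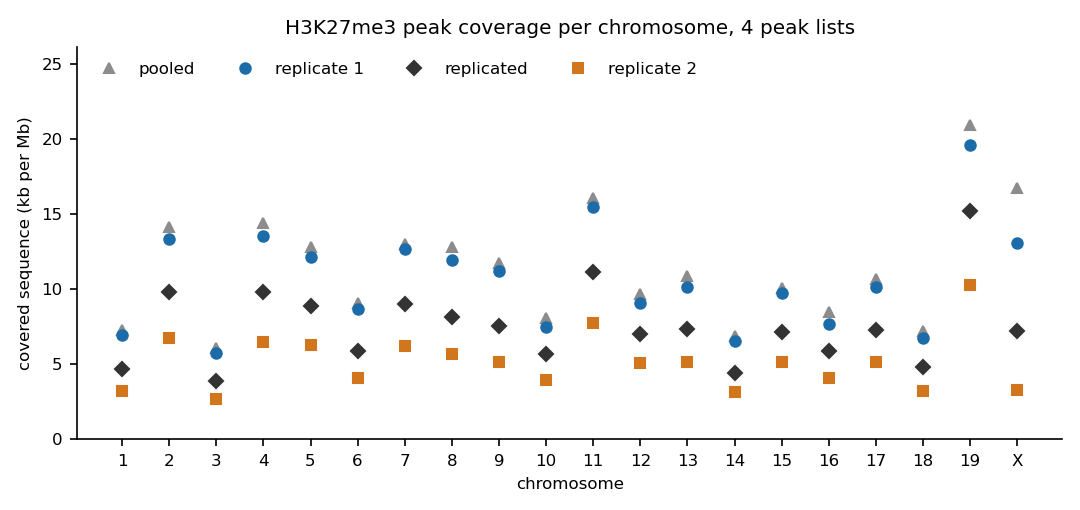
Length covered by peaks per Mb (y axis, kb) for each autosome and X (x axis) in the 4 peak lists. Chromosome 19 is highest and chromosome 3 lowest among autosomes in each list, and X lies above the autosomal median in replicate 1 and below it in replicate 2.

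Narrow peaks joined across gaps of up to 3 kb formed 9006 domains, of which 610 spanned at least 10 kb. The count was 1122 in replicate 1 and 513 in replicate 2, 363 with gaps of up to 1 kb and 1139 with gaps of up to 10 kb. The widest domain, 176 kb, held the Hoxc genes from Hoxc13 to Hoxc4 (chromosome 15, 102895147 to 103071358; 84.3% covered, replicates 75.0% ± 9.27, SD, n = 2). The second, 152 kb, ran from within Hoxa3 to Evx1 (chromosome 6, 52179309 to 52331584; 80.5% covered). The third, 148 kb, lay over Dbx1, a homeobox gene of spinal and hindbrain interneuron progenitors, and overlapped Htatip2 (chromosome 7, 49613523 to 49761782; 84.6% covered, replicates 74.4% ± 9.52). The fourth, 120 kb, lay on X over Iqsec2, a synaptic exchange factor gene (152111449 to 152230957), and was less dense, with 51.7% covered and replicate values of 37.9% ± 16.8. The fifth, 111 kb, held Hoxb9 to Hoxb3 (chromosome 11, 96228377 to 96339771; 71.5% covered). A domain from Evx2 to Hoxd4 without Hoxd1 (107 kb), a stretch of chromosome 5 with no protein-coding gene (101489888 to 101589154, 99.3 kb), Pax3 (95.3 kb), Rnf220 (90.4 kb) and Tbx3 (70.9 kb) completed the 10 widest.

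Replicate 1 alone marked 1257 genes and replicate 2 alone 161. By signal, the first of replicate 1's own were Dctn3 (5.01), Flvcr2 (4.82), Procr (4.63), Pls1 (4.6) and Grhl3 (4.52), an epidermal regulator, against a highest signal of 9.44 in that list. Those of replicate 2 were Arntl2 (4.51), the neurofilament gene Nefl (3.68), Rad18 (3.67), 1700016K19Rik (3.64) and Nppc (3.62), against a highest signal of 8.28. All of these genes except 1700016K19Rik and Nppc were marked in the replicated list. The other replicate could still have peaks near the TSS. Replicate 2 covered 30.9% of the 10 kb window at Dctn3, 16.7% at Grhl3 and 5.01% at Pls1, but 0% at Flvcr2 and Procr. Replicate 1 covered 22.5% at Nefl, 9.46% at Nppc and 2.61% at Arntl2, but 0% at Rad18 and 1700016K19Rik.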

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

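The test of the number of peaks called in replicate 1 was chosen after the result was seen, as was the test that left out Meis and Pbx genes; the other tests here were set before their results were seen. The pooled list, of which the replicated peaks are a part and which otherwise served as an alternative, held 19610 peaks (28.7%) that met no peak of either replicate's own list, above the 3 peaks set as the floor for a count of 0; 884 of them are in the replicated list. Within that list their median −log10 p was 3.70 against 4.98 for the other peaks, and their median width was 200 bp against 318 bp. X held 16.0% of them against 12.3% of the others, and 4.83% lay at promoters. They marked 307 genes that were marked in neither replicate's own list nor in the replicated list.

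Peaks on X took 10.8% of the replicate 1 list and 6.76% of the replicate 2 list. A longer list reaching further into weak peaks was tested by taking the 28948 top-ranked peaks of each: X then held 10.5% (95% Wilson interval 10.1 to 10.8, counting error only) and 6.76% (6.47 to 7.05), a ratio of 1.55, which argues against list length as the whole cause. A candidate explanation is the inactive X of female embryos, which carries H3K27me3, with pools that might differ in sex ratio; the ratio is not given in the sources used here. Of 10 genes known to escape inactivation, 4 (Pbdc1, Car5b, Mid1 and Bgn) held a replicate 1 peak in their body, against 236 of 938 other X genes (Fisher's exact p = 0.284), which leaves this open because the genes were too few. Depth and the different control files stay open as well, and no biological explanation was tested between groups, since the samples form 1 group.

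Of the 26040 replicated peaks, 10005 (38.4%) were missing from at least 1 replicate's own list. Their median −log10 p was 5.32 against 8.10 for peaks met by both, a difference of −2.78 (95% bootstrap interval −2.82 to −2.77), and 8591 lacked a peak of the replicate 2 list against 2298 lacking one of replicate 1. Whether they are weak peaks that calling on the pooled reads recovers stays open: that p comes from the same reads that decided each replicate's calls, and the replicate 2 list was shorter (28948 peaks against 63373), so both values were to be expected in any case. On X, 41.8% of replicated peaks met both lists, against 63.8% on autosomes. No biological explanation was tested.

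Hindbrain regulators were less covered than forebrain regulators, by −16.1 percentage points. The values argue against the CpG observed/expected ratio near the TSS as the cause, since adjusting for it removed −1.20% of the difference (95% bootstrap interval −19.6 to 10.03) and left −16.3 points (SE 6.15). The ratio was the highest within 500 bp of any TSS of a gene, with means of 0.762 (hindbrain) and 0.739 (forebrain). CpG content over the 10 kb window was not tested. The number of annotated TSSs per gene removed −2.20% (−17.2 to 11.1) and left −16.5 points (SE 6.13). Leaving out Meis1, Meis2, Pbx1 and Pbx3 removed 46.2% and ended the call, but they were picked because each was at 0% and were left out of the hindbrain list alone, so the difference had to shrink and the test decides nothing about the other genes. Expression of hindbrain genes in the tissue stays open as an explanation, and no biological explanation was tested.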

How the results depend on the processing

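The comparisons using replicated peaks met by both replicates' own lists, the hindbrain list without Meis and Pbx genes, and paralogs 1-5 without Hoxa2 and Hoxb2 were chosen after the results were seen; the other alternatives were planned. The Hox covered-share difference kept its direction and its side of the threshold in the 6 alternatives run, from −40.1 to −24.4 points, as did the CpG odds ratio in the 9 run, from 1.27 to 1.93. The hindbrain minus forebrain covered share fell to −8.68 points without the Meis and Pbx genes and no longer passed, a fall set by construction, since genes at 0% were left out of 1 list. The marked-share difference no longer passed at −16.2 points with TSS windows of 500 bp on each side, −11.4 with 2500 bp, −17.1 with 50% of the window covered, −9.57 without the Meis and Pbx genes, and −16.2 to −14.3 with each replicate left out. Requiring 50% of the window left 1353 marked genes, a stricter rule by construction. Of 319 list alternatives, 301 kept their call, 13 lost one, 3 gained one and 2 changed direction without passing the threshold: keratins (odds ratio 1.15 without replicate 2, within 0.957 to 1.15 with each replicate left out) and pan-neuronal genes (1.1 among high-CpG promoters). High-CpG promoters alone left 1 list called less often marked, since the other 3 had 3 or fewer members there. With the pooled list, the X to autosome ratio was 1.57, the promoter share of peaks 9.03% and wide domains 1278; with each replicate left out, the promoter share was 9.47% to 14.7% and wide domains 513 to 1122. Wide domains numbered 363 with gaps of up to 1 kb and 1139 with gaps of up to 10 kb, by construction. The 50% of peaks with the best p had a median width of 691 bp, and between the replicates they shared 29.9% and 77.5% of peaks (replicate 1 and 2) with a Jaccard index of 0.349. Requiring 50% of a peak's width gave 20.0% and 65.5%, and equal numbers of top-ranked peaks 47.0% and 60.4% with an index of 0.403. Among covered shares of 237 named genes, 1080 of 1422 alternatives moved by less than the replicate SD, but 139 genes moved by more without replicate 1 and 95 with windows of 2 kb on each side, against 15 to 41 in the other 4 settings. These counts are partly set by construction. Genes at 0% in every list, such as Tubb3, could not move, and the SD came from the replicate lists that also served as alternatives. Where no construction is named, the cause was not tested. Depth is unknown, so an unmarked promoter is one without a called peak and not one without the mark. No paired analysis was possible because the samples form 1 group.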

Other observations

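All tests in this part were chosen after the report's results were seen. Stems of most families in the fixed lists, such as Fox, Sox, Wnt, Zfp and Olfr, and the stems Gm and Rik were left out beforehand. The stem Cdkn was kept, as were fixed-list genes with other stems, among them solute carrier and ribosomal protein genes. Those genes therefore entered both sets of tests. Grouping the remaining genes by their stem, the letters before the first digit of the symbol, gave 251 families of at least 10 genes, of which 11 were marked more often than other genes and 3 less often (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the families). Genes whose symbols have no digit after the stem were not counted, so a family can lack members. Collagen genes were marked at 24 of 45 (adjusted exact p = 1.76e-08; 29 in replicate 1 and 24 in replicate 2), among them Col1a1, Col1a2 and Col2a1, which encode fibrillar collagens of connective tissue and cartilage. Integrin alpha genes with a number in their symbol were marked at 8 of 12 (adjusted exact p = 0.00171), Kcnk genes, for potassium channels that set the resting potential, at 8 of 14 (adjusted exact p = 0.00491), and serotonin receptor genes at 7 of 14 (adjusted exact p = 0.0286), including Htr1a and Htr2c. Solute carrier genes were marked at 77 of 371 (adjusted exact p = 0.00158). Ribosomal protein genes of the large subunit (0 of 54, adjusted exact p = 0.0401), their mitochondrial counterparts (0 of 49, adjusted exact p = 0.0407) and histone genes (1 of 67, Hist1h1b, adjusted exact p = 0.0457) were marked less often; replicate 1 marked 2 of the ribosomal genes.

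Long noncoding genes, which no list above held, were also counted. Of 5305 lincRNA genes, 311 (5.86%) had a promoter peak, 10.5% in replicate 1 and 5.47% in replicate 2. Among the 4640 whose TSSs all lay over 5 kb from any coding TSS the share was 4.50%, 9.25% in replicate 1 and 4.22% in replicate 2. Of 2958 antisense genes, 271 (9.16%) were marked, 13.9% in replicate 1 and 8.96% in replicate 2, and of the 1583 far from coding TSSs 51 (3.22%), 7.08% in replicate 1 and 3.54% in replicate 2. The lincRNA gene of the highest signal far from a coding TSS was Gm53 (6.96), between Hoxb13 and Hoxb9 (chromosome 11, 96251105 to 96264868).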
